A study of Homo sapiens with 9 samples.

How the data were processed

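RNA was extracted from H1 human embryonic stem cells with a column kit and DNase treatment, and libraries were made with a stranded total RNA kit after ribosomal RNA depletion, per the labels' protocols. The 9 libraries form 2 groups by their titles, 4 of the control clone and 5 of the clone with the HERVHlin knockout on chromosome X. Per the submitters' processing notes, fastp, kallisto and DESeq2 were used with the hg38 build, without versions, order or role. The annotation release, and whether counting used the strand, are not given in the sources used here.

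The deposited table has 60829 rows and 1 signal column per library, which holds gene counts that the authors divided by 1 size factor per library (normalized counts). Within the tolerance of 1e-06, 100% of these values were whole multiples of the smallest value above 0 in their library, so reads were recovered by division, and no other columns of per-sample values were used. The authors' mean signal, log2 fold change with its standard error, test score, p-value and adjusted p-value stand in the same deposited table. DESeq2 on the recovered reads, with the group as the only term, gave the authors' log2 fold changes to within 1.4e-05. The authors also marked rows in the deposited table, among them 3 as knocked out and others by overlap with a LIN28 knockout, EMT, differentiation, defence and testis genes, and the way these marks were made is not given in the sources used here. Of the rows, 111 have gene.human_ IDs and 69 have miRBase-style IDs. No rows for repeat families were recognised by name, so the planned comparison of repeat families was not run.

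The design written before the data were examined planned edgeR for counts and limma for normalized values. As the values were normalized counts, the main test was limma (version 3.58.1, R 4.3.3) with a mean-variance trend on log2(value + 1), with the group as the only term and all 9 libraries. Fold changes on this scale understate the change of genes with few reads. Rows were kept by edgeR's filterByExpr on the recovered reads with a minimum count of 10, which left 27777. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The count test on the recovered reads, edgeR's quasi-likelihood test (version 4.0.16), was an alternative and called 151 genes. DESeq2 (version 1.42.0) was another alternative.

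Gene lists, 25 in number and fixed before the data were examined, cover pluripotency, naive and primed states, LIN28 and let-7, HERVH-associated transcripts, lineage and fibroblast markers, retroelement restriction, interferon, stress, signalling, proliferation, imprinting, a recurrently gained segment, histones, mitochondrial and germline genes. They were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, and adjusted over the lists. Lists were also compared with 10000 random lists matched on mean expression, drawn from coding genes for most lists. Single sums were compared by two-sided exact permutation tests on log2 values over the 126 splits of the libraries into 4 and 5.

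Gene positions came from GENCODE 29 (GRCh38), matched on Ensembl IDs without the version, for 58337 rows and 26967 of the tested ones. Calls per chromosome and direction were tested with Fisher's exact test over 22 autosomes and chromosome X.

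The genes named were set by a rule written before the data were examined. It takes the knocked-out feature, here the 3 marked rows, and 12 genes whatever their values (LIN28A, LIN28B, POU5F1, NANOG, SOX2, DNMT3B, ESRG, HMGA2, IGF2BP1, IGF2BP3, TRIM71 and TRIM28). It adds the 10 largest rises and 10 largest falls among called genes with a mean of at least 50 normalized counts, non-overlapping libraries and a gene symbol, and up to 4 called members of each list. As the gene.human_ IDs are not paired with names, at most 2 of them are printed.

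The labels file the replicate number under a batch tag, so libraries with the same number were taken as paired. Deviations from the clone means correlated at 0.07, 0.02, 0.25 and 0.33 for replicates 1 to 4, and each control library correlated best with the knockout library of its own number. The reverse did not hold for knockout 2, which correlated at 0.13 with control 3 and at 0.02 with control 2. Knockout 5 has no partner. The fit with the replicate number as a block was an alternative, in which knockout 5 takes a term of its own and adds nothing to the fold change, so that 8 libraries set it.

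Depth was 19838682 to 31192630 recovered reads per library, of which the 10 largest rows of each library took 27.4% to 51.3%. A group with 0 reads was given a floor of 3 reads over the group, which covers counting error only. The scripts were tested on simulated data for the knockout against control comparison, drawn for 27777 rows with 200 changed genes. The changed genes were taken from rows with a mean of at least 50 normalized counts. Each gene was drawn independently, so the simulation held no swings shared between genes. Limma recovered 20 of 100 genes changed 2-fold and 77 of 100 changed 4-fold with 6 false calls, and DESeq2 recovered 48 and 92 with 100 false calls. Alternatives in scaling, filter, pseudocount, tool, threshold and block, and each library left out in turn, are given in the closing section.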

Results

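Total RNA was sequenced, after removal of ribosomal RNA, from H1 cells, an established line of human embryonic stem cells. One clone carried a knockout on chromosome X that the labels name HERVHlin, and the other was its control clone. HERVH is a family of endogenous retroviruses that is transcribed in human pluripotent cells. The series title ties the locus to pluripotency, retroelements and the LIN28A/let-7 pathway, and the comparison asks which transcripts differ between the clones. The control clone gave 4 libraries and the knockout clone 5, each from a successive passage of 1 clone, which the series design treats as technical replicates although the titles call them biological. All p-values therefore measure the spread between passages of 1 clone per group. The growth label names a stem cell medium, whereas a treatment label calls the cells differentiated.

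The reads recovered per control library numbered 23721382, 21767416, 30388797 and 19838682 for replicates 1 to 4. For knockout replicates 1 to 5 they numbered 31192630, 25174625, 21434888, 22963423 and 22854413. Protein-coding genes took between 26.3% and 50.8% of the reads of a library. The highest share was in control 3, where the median highly expressed coding gene lay 0.69 above its mean over all libraries on the log2 scale. Rows with miRBase-style names took 31.4% of the reads of knockout 1 and as little as 5.28% in control 3.

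The authors' table marks 3 rows as the knocked-out feature, and it does not say which of them lies at the locus on chromosome X. The row gene.human_00015544 fell from 2700 ± 1198 normalized counts in the control clone (SD, n = 4) to 57.5 ± 18.4 in the knockout clone (SD, n = 5). Its log2 fold change was -5.49 (SE 0.38, limma adjusted p = 0.00018), and it passed with any 1 of the 9 libraries left out. The row gene.human_00001528 fell from 698 ± 299 to 116 ± 35.9 normalized counts (log2 fold change -2.51, SE 0.36, limma adjusted p = 0.016), but missed the threshold without control 1 (adjusted p = 0.059) or control 2 (adjusted p = 0.067). The third marked row measured 2403 ± 841 normalized counts in the control clone and 1452 ± 307 in the knockout clone, a difference that did not pass (log2 fold change -0.68, SE 0.25, limma adjusted p = 0.44). The summed 3 rows stood at 5800 ± 2290 (SD, n = 4) against 1626 ± 333 (SD, n = 5) (two-sided exact permutation p = 0.0079, the smallest that 126 splits can give). This test ignores the pairing of replicate numbers. Of the 100 splits drawn for the closing section, only 15 part all 4 pairs, too few for a share under 0.05.

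The other rows of the same naming series moved the same way. Of 99 tested rows named gene.human_ without the mark, 17 fell and 0 rose (63 lower when adjusted over the list alone), 95 had a negative log2 fold change, and the median was -1.30. Together the 108 such rows held 122768 ± 45478 normalized counts per control library (SD, n = 4) and 45384 ± 10326 per knockout library (SD, n = 5), 2.71 times less (two-sided exact permutation p = 0.0079, the smallest possible, again without the pairing). As a set they were lower in limma's camera test with an estimated correlation as well (unadjusted camera p = 0.0072, adjusted p = 0.015 over 8 lists added after the values were seen). The 8 lists include those that the authors marked on these samples, whose small p-values lower the adjusted p. The IDs are not paired with names in the sources used here, so no element is named, and how reads of related copies are divided among the rows was not measured. With the replicate number as a block 7 of these rows fell, and the count was 10 without control 1, 10 without control 3 and 28 without control 4. ERVH-1, a transcript with a symbol of its own that was picked after its value was seen, fell from 576 ± 256 to 85.8 ± 35.0 normalized counts (log2 fold change -2.66, limma adjusted p = 0.025), but it passed in 2 of 9 fits with 1 library left out (highest adjusted p = 0.10) and missed the threshold with the block (0.056).

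**Figure D1:**
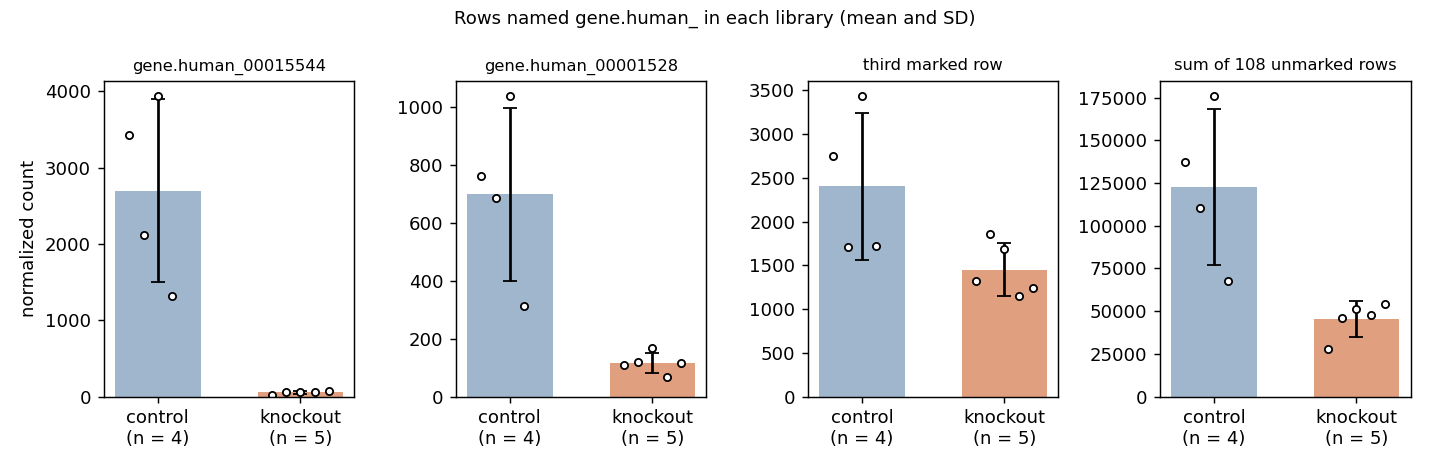
Normalized counts of the 3 marked rows and the summed 108 unmarked gene.human_ rows, with each library as a point, the mean as a bar and the SD as a line, for the control clone (n = 4) and the knockout clone (n = 5). The control clone's mean was 2700 against 57.5 for gene.human_00015544 and 122768 against 45384 for the unmarked rows, with no overlap of the libraries.

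Among genes with symbols, several were nearly absent from 1 clone. In the knockout clone, DNAJC15, which encodes an inner mitochondrial membrane cochaperone, rose from 0.840 ± 0.975 to 112 ± 20.8 normalized counts (log2 fold change 6.09, SE 0.41, limma adjusted p = 0.00015, chromosome 13, 43023203 to 43114224). PUS7L, a pseudouridine synthase homologue, rose from 19.9 ± 10.5 to 353 ± 36.3 (log2 fold change 4.21, SE 0.31), and CTSF, the lysosomal protease cathepsin F, from 12.8 ± 3.26 to 121 ± 40.9 (3.11, SE 0.30). CAT, the peroxisomal enzyme catalase, rose from 110 ± 9.60 to 277 ± 16.1 (1.33, SE 0.13). RNY4P24, a Y RNA pseudogene inside THSD1 that overlaps none of its exons, had 0 reads in the 4 control libraries and 180 ± 85.6 normalized counts in the knockout clone, at least 216-fold higher against a floor of 3 reads over the group. As a copy of a short RNA it can share reads with its relatives, and the pseudogene FAR2P3 (log2 fold change 3.27) likewise. The other rises named by the rule were HMX2 (2.22), ZNF439 (1.80), MMP17 (1.28) and STXBP5L (1.23), all past limma's adjusted p of 0.05. With the replicate number as a block, 5 of these 10 missed the threshold: FAR2P3 (limma adjusted p = 0.13), HMX2 (0.11), ZNF439 (0.12), MMP17 (0.20) and STXBP5L (0.15). With 1 library left out, HMX2 passed only without control 3 (highest limma adjusted p = 0.16) and MMP17 only without knockout 3 (0.17). STXBP5L passed only without control 3 or control 4 (highest limma adjusted p = 0.12) and ZNF439 only without control 1, control 3, control 4 or knockout 3 (0.067). FAR2P3 missed the threshold without control 1 (limma adjusted p = 0.053) or knockout 5 (0.051).

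More genes were lower in the knockout clone. TMLHE, the first enzyme of carnitine synthesis, fell from 139 ± 31.8 to 2.36 ± 1.5 normalized counts (log2 fold change -5.54, SE 0.48, limma adjusted p = 0.0010, chromosome X, 155490115 to 155669944). PIWIL2, a PIWI protein that acts in transposon silencing in the germline, fell from 111 ± 33.0 to 4.98 ± 2.04 (-4.25, SE 0.35, limma adjusted p = 0.00070). The zinc finger gene ZNF717 fell from 206 ± 36.1 to 5.76 ± 1.76 (-4.97, SE 0.28), and the linker histone gene H1-1 from 1540 ± 1478 to 16.4 ± 7.98 (-5.93, SE 0.69). MIR764 (chromosome X, 114639435 to 114639519), which lies within HTR2C and overlaps none of its exons, held 166 ± 86.8 normalized counts in the control clone and 0 reads in the 5 knockout libraries, at least 291-fold lower against a floor of 3 reads over the group. HTR2C, looked up after that, measured 89.7 ± 28.2 and 25.7 ± 12.4 normalized counts (log2 fold change -1.84, limma adjusted p = 0.067). The remaining falls named by size were TMEM230P1 (-5.37), MIR924HG (-4.00), SCGB3A2 (-3.27), GDA (-2.73) and HSPB2 (-2.71). Exons of ZNF717 overlap LINC00960 and those of HSPB2 overlap CRYAB, and TMEM230P1 is a processed copy, so their reads may be shared. With the replicate number as a block, H1-1 (limma adjusted p = 0.052), PIWIL2 (0.054), GDA (0.054) and HSPB2 (0.15) missed the threshold. With 1 library left out HSPB2 passed only without knockout 1 (highest limma adjusted p = 0.16).

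**Figure D2:**
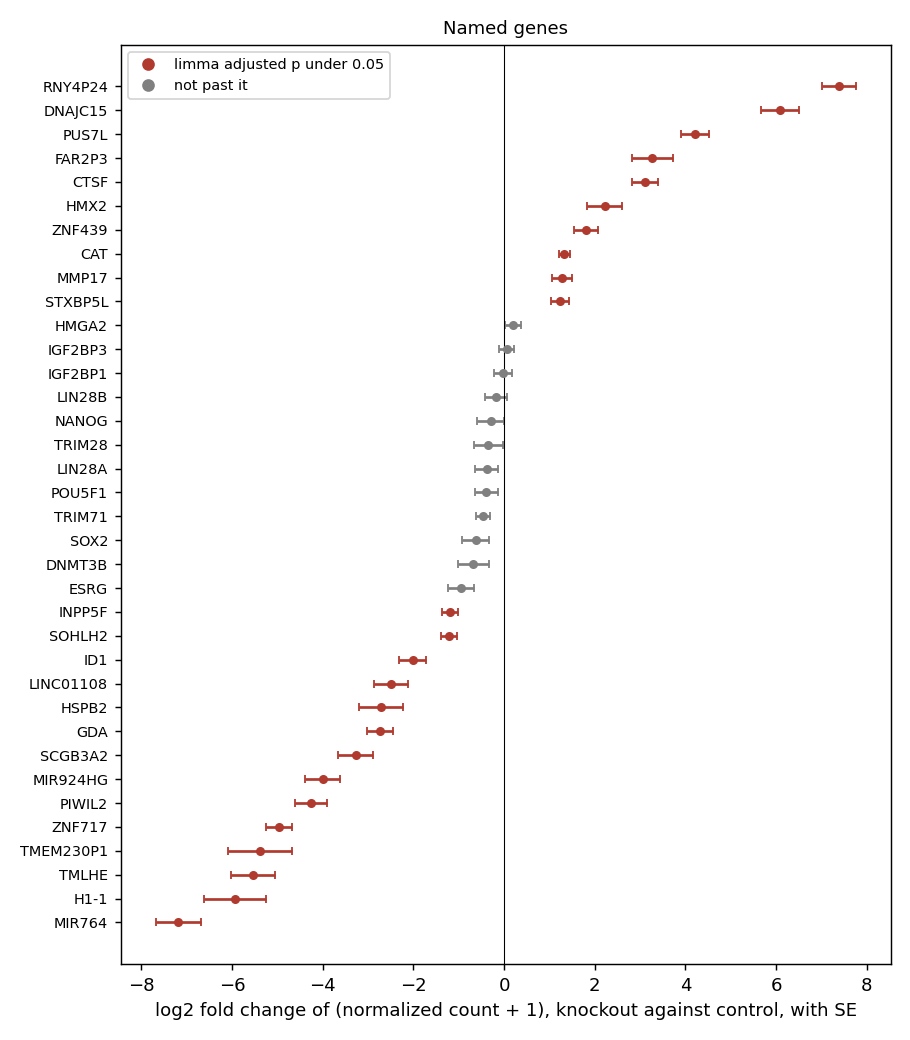
Log2 fold change of normalized count + 1, knockout clone (n = 5) against control clone (n = 4), with its SE, for the named genes that have symbols. Red points passed limma's adjusted p of 0.05 and grey ones did not, and values run from 7.38 for RNY4P24 to -7.18 for MIR764, whose fitted sizes depend on the pseudocount because 1 clone had 0 reads.

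Over all rows, limma called 150 of 27777 tested at an adjusted p under 0.05, 32 higher and 118 lower in the knockout clone, while 2397 had an unadjusted p under 0.05. Of these, 77 were protein-coding (18 higher, 59 lower) and 33 were long noncoding RNAs (3 higher, 30 lower). The libraries of the clones did not overlap for any of the 150, nor for 3.95% of all tested rows, where chance gives 1.59%. The count was 43 with the replicate number as a block and 593 with DESeq2. It was 93 without control 1, 80 without control 2, 94 without control 3, 95 without knockout 2, 79 without knockout 4 and 80 without knockout 5, and 64 of the 150 passed in all 9 such fits.

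Transcripts associated with HERVH elements had a median log2 fold change of -0.89 over 12 tested (camera adjusted p = 2.7e-10 with the preset correlation, and adjusted p = 0.32 with an estimated correlation). Of these, SCGB3A2 fell from 477 ± 234 to 46.9 ± 20.9 normalized counts and LINC01108 from 64.9 ± 20.1 to 11.02 ± 5.24 (log2 fold changes -3.27 and -2.49, limma adjusted p = 0.0051 and 0.020). When adjusted over the list alone 6 members were lower, and the authors' deposited table calls 4 lower. ESRG, a long noncoding RNA of this list, measured 7945 ± 3598 and 3938 ± 956 normalized counts (-0.95, SE 0.29, limma adjusted p = 0.30). LINC01108 missed the threshold with the block (limma adjusted p = 0.081), and with 1 library left out it passed only without control 4, knockout 1 or knockout 3 (highest adjusted p = 0.091).

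Genes of the pluripotent state had lower values without single calls by limma. Of 25 tested pluripotency genes, 0 passed over all genes with limma or edgeR (9 lower at an unadjusted limma p under 0.05), 5 were lower when adjusted over the list alone (UTF1, DPPA2, NODAL, GDF3 and PRDM14), 23 had a negative log2 fold change, and the median was -0.58 (camera adjusted p = 5.0e-09, and adjusted p = 0.32 with an estimated correlation). DESeq2 called 3 lower, and the authors' deposited table calls UTF1, DPPA2 and NODAL lower (adjusted p = 2.8e-05, 0.00076 and 0.026). POU5F1 stood at -0.39 (SE 0.26), NANOG at -0.29 (SE 0.30), SOX2 at -0.63 (SE 0.29) and DNMT3B at -0.68 (SE 0.35), none past the threshold (limma adjusted p between 0.59 and 0.82). Without control 3, the library with the highest protein-coding share, these came to -0.16, -0.13, -0.38 and -0.36 and the list's median to -0.36. Under quantile normalization POU5F1 stood at -0.03. In the list of TGF-beta, NODAL and BMP signalling, ID1, a target of BMP signals, fell from 587 ± 244 to 140 ± 42.2 normalized counts (-2.02, SE 0.31, limma adjusted p = 0.022). It missed the threshold without control 2, control 3, knockout 1, knockout 2, knockout 4 or knockout 5 (highest adjusted p = 0.094). In that list 9 of 21 members were lower when adjusted over the list alone, with a median of -0.46 (camera adjusted p = 3.4e-07, and adjusted p = 0.32 with an estimated correlation), which came to -0.28 without knockout 4.

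Camera also gave lower values for mesendoderm and mesoderm markers (9 tested, 0 called, 4 lower when adjusted over the list alone, median -0.80), trophectoderm and amnion markers (4 tested, 0 called, 2 over the list alone, -0.70) and naive pluripotency genes (13 tested, 0 called, 2 over the list alone, -0.50), each with an adjusted p = 0.32 with an estimated correlation. The unfolded protein list (20 tested, median -0.45) had an adjusted p = 0.38 with an estimated correlation, and the mitochondrially encoded genes (13 tested, -0.89) and the immediate early and heat shock genes (20 tested, -0.33) an adjusted p = 0.53 with an estimated correlation, with 0 members called in each, also when adjusted over the list alone. Without 1 library the medians moved by over 1.5 times for the mitochondrial genes (-0.44 without knockout 1), the immediate early and heat shock genes (-0.16 without control 3) and the naive genes (-0.32 without control 1). The mitochondrial median was -1.17 without knockout 5. Mitochondrial rows took 3.15% of the reads in knockout 5, the highest share of any library, and 0.61% in knockout 1, the lowest. EdgeR called 0 members of these 6 lists. The authors' deposited table calls 4 mesendoderm and mesoderm, 1 trophectoderm and amnion, 2 naive and 1 unfolded protein gene lower, and DESeq2 called 1, 1, 2 and 1. Thus 9 of 25 lists passed with the preset correlation, all lower, and 0 with an estimated one. The naive list missed the threshold with the block (adjusted p = 0.085) and without control 1 (0.12), and 50 of 100 splits of the 9 libraries into groups of 4 and 5 gave at least 9 lists.

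**Figure D3:**
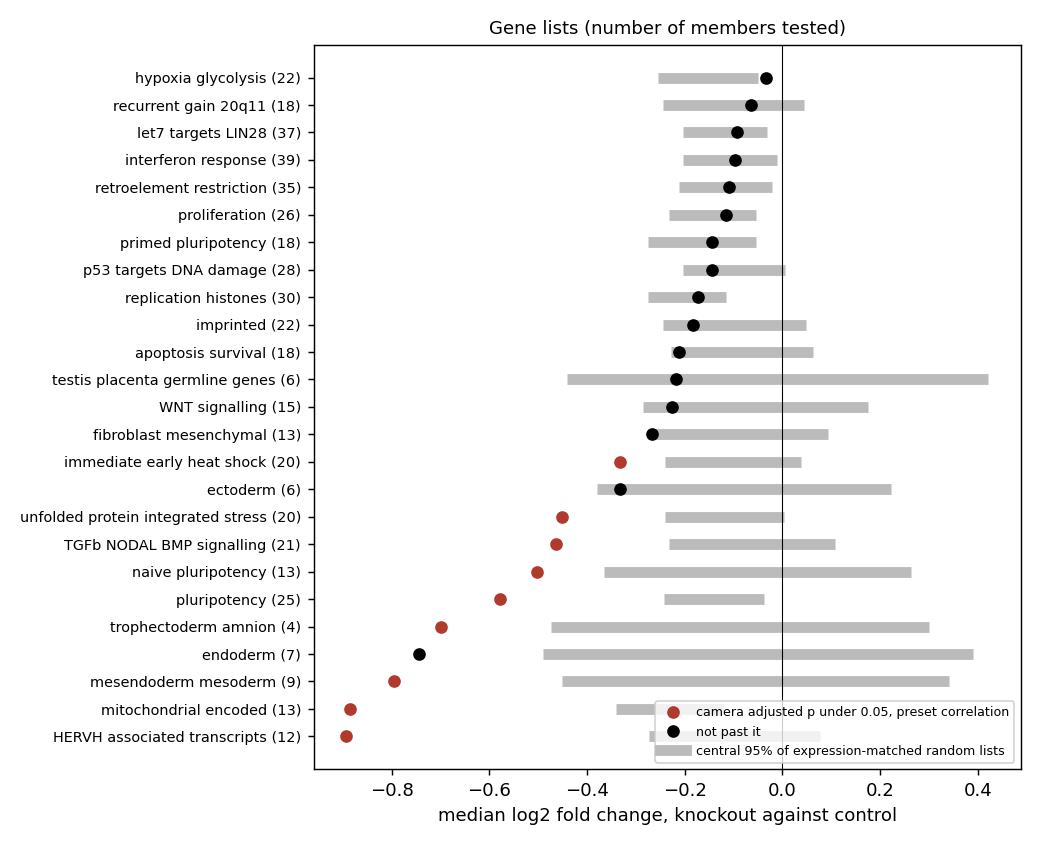
Median log2 fold change, knockout against control, of the tested members of each of 25 gene lists (points, red where camera's adjusted p with the preset correlation passed 0.05), with the central 95% of medians of random lists matched on expression (grey bars). The HERVH-associated transcripts had the lowest median, -0.89, and the LIN28 and let-7 list, at -0.09, lay inside its bar.

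Genes of the LIN28 and let-7 pathway did not pass with limma. LIN28A, an RNA-binding protein that blocks let-7 maturation, measured 13335 ± 5337 and 9804 ± 1745 normalized counts (log2 fold change -0.38, SE 0.26, limma adjusted p = 0.75, and -0.14 without control 3), and LIN28B stood at -0.18 (SE 0.24, and from -0.31 to 0.07 over the settings tried). The let-7 targets HMGA2 (0.19, SE 0.18), IGF2BP1 (-0.02, SE 0.19), IGF2BP3 (0.06, SE 0.17) and TRIM71 (-0.46, SE 0.15) did not pass either. Of 37 tested members of the LIN28 and let-7 list 0 were called by limma or edgeR (1 higher and 2 lower at an unadjusted limma p under 0.05), also 0 when adjusted over the list alone, and the median was -0.09 (camera adjusted p = 0.19), but the list was lower without control 4 (adjusted p = 0.017), the only call among the 9 fits with 1 library left out. It had an adjusted p = 0.83 with an estimated correlation, and its direction turned upward without control 3 (adjusted p = 0.19) and under quantile normalization (0.37). Its median ran from -0.23 without control 4 to 0.07 without control 3. The authors' deposited table calls PRTG higher and IL6R lower in this list (adjusted p = 0.0077 and 0.037), and DESeq2 called 1 higher. The authors' table carries a mark for overlap with a LIN28 knockout, of which 96 rows were tested, 4 higher and 8 lower, with a median of -0.68 (20 higher and 76 lower when adjusted over the list alone). That list was chosen on these samples and is not independent evidence of its direction.

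Among genes that restrict retroelements, PIWIL2 was the single call of 35 tested (2 lower when adjusted over the list alone, median -0.11, camera adjusted p = 0.055), and the list was lower in 5 of 9 fits with 1 library left out, those without control 1, control 4, knockout 1, knockout 2 or knockout 3 (smallest adjusted p = 0.013). It had an adjusted p = 0.65 with an estimated correlation, 0.16 with the block and 0.85 under quantile normalization. Its median was 0.02 without control 3. DESeq2 and the authors' deposited table each have 2 lower members. TRIM28, a corepressor of retroelements, stood at -0.35 (SE 0.32, limma adjusted p = 0.81, and -0.05 without control 3). Of 39 tested interferon response genes 0 were called by limma (2 higher at an unadjusted p under 0.05), also 0 when adjusted over the list alone, and 0 by edgeR, DESeq2 or the authors' deposited table. Their median was -0.10 while camera's direction was upward (adjusted p = 0.98), and with the block the list was higher (adjusted p = 0.013, and adjusted p = 0.99 with an estimated correlation and no block). The list's direction was upward in 5 and downward in 4 of the 9 fits with 1 library left out, none of which passed (lowest adjusted p = 0.052). Its median ran from -0.35 without control 4 to 0.17 without knockout 5. Among other lists, INPP5F (log2 fold change -1.19) was the call of the imprinted list, 1 of 22 tested members. SOHLH2, a germline transcription factor gene whose exons overlap a readthrough gene, was 1 of 6 in the germline list (-1.21). Both missed the threshold with the block (limma adjusted p = 0.095 and 0.16). With 1 library left out INPP5F passed only without control 4 (highest limma adjusted p = 0.084), and SOHLH2 missed the threshold without control 1, control 3, knockout 3, knockout 4 or knockout 5 (highest 0.066). ID1 was the single call of 18 on the recurrently gained segment of chromosome 20, and HMX2 the single call of 18 primed pluripotency genes.

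Of the other lists, 0 members were called by limma in those for ectoderm (camera adjusted p = 0.53), endoderm (0.055), fibroblasts (0.059), p53 targets (0.055), proliferation (0.46), apoptosis (0.076), hypoxia and glycolysis (0.98), WNT signalling (0.064) and replication histones (0.076). When adjusted over the list alone, 1 ectoderm gene (MAP2) was higher, and 1 endoderm and 2 WNT genes were lower. DESeq2 and the authors' deposited table have the same numbers for these 3 lists and 0 for the other 6. EdgeR called 1 lower WNT gene, and 0 to 4 members of each list had an unadjusted limma p under 0.05. The same adjustment gave 2 higher and 3 lower primed pluripotency genes, 2 lower genes of the chromosome 20 segment, and INPP5F and SOHLH2 in their lists. Camera gave adjusted p = 0.29 for imprinted genes, 0.15 for germline genes, 0.055 for the chromosome 20 segment and 0.71 for primed pluripotency, whose median (-0.14) and mean (0.01) differed in sign, as they did for hypoxia and glycolysis (-0.03 and 0.03). The primed median came to 0.05 without control 3, -0.28 without control 4 and -0.09 without knockout 4. Camera's direction for that list was upward without control 3 (adjusted p = 0.16) and under quantile normalization (0.083). The hypoxia and glycolysis median ran from -0.17 to 0.03 with 1 library left out. With all libraries it stood at percentile 98.86 of the medians of random lists matched on expression. That is above their central range (-0.26 to -0.05), although camera did not pass. Replication histones were lower with the block (adjusted p = 0.0086) and without control 1 (6.4e-05), control 4 (0.016) or knockout 3 (0.0016), but had an adjusted p = 0.83 with an estimated correlation. Their direction turned upward without control 3 (adjusted p = 0.069), the library with the highest protein-coding share, and under quantile normalization (0.25). With 1 library left out, camera gave lower values in 3 of 9 fits each for endoderm, fibroblasts, p53 targets, WNT signalling and the chromosome 20 segment, and in 2 for apoptosis, while no list passed with an estimated correlation (smallest adjusted p = 0.32).

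By position, chromosome X held 10 of the called genes, 3 higher and 7 lower, against 1.01 and 3.02 in proportion to its tested genes. Chromosome 5 held 10 lower calls against 4.54 in proportion, and chromosome 12 held 5 higher calls against 1.74. Of the 10 lower calls on chromosome 5, 4 were clustered protocadherin genes, which the test counts as separate genes. None of 46 tests over 23 chromosomes passed (Fisher's exact test, smallest adjusted p = 0.49), although these 3 had an unadjusted p under 0.05. The lower calls on chromosome 5 passed without control 3 (Fisher's exact test, adjusted p = 0.0022), knockout 2 (0.048), knockout 3 (0.047), knockout 4 (0.044) or knockout 5 (0.012), and those on chromosome X without knockout 3 (0.047).

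The authors' deposited table calls 781 rows at an adjusted p under 0.05, 200 higher and 581 lower in the knockout clone. A separate mark in it labels 1533 rows as significant, by a rule not given in the sources used here. At an adjusted p under 0.05 it calls 713 of the rows tested here, which include all 150 called by limma, with the same direction for each. For TMLHE the authors' deposited table gives a log2 fold change of -5.88 and for DNAJC15 of 7.13, and for LIN28A one of -0.44 with an adjusted p of 0.72. DESeq2 on the same tested rows shared 584 calls with it. All these calls come from the same libraries, so the shared calls and directions are not independent support.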

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

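Values were looked at again where 1 library of a clone lay far from the rest of its clone on the log2 scale, measured as its gap to the nearest library over the clone's range. Over 90 such groups of 4 or 5 libraries 5 passed, and chance alone flags about 1 in 20 groups, so 5 is about the number chance gives.

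In knockout 1 the marked row gene.human_00015544 stood at 25.9 normalized counts against 58.6 to 73.0 in the other knockout libraries. TMLHE had 0 reads in knockout 2 against 2.21 to 3.83 normalized counts in the others. In control 2 ZNF717 stood at 152 normalized counts against 223 to 225 in the other control libraries. Control 3 held 1387 normalized counts of HMGA2 against 816 to 861 in the other control libraries, and 48.3 of HMX2 against 13.98 to 17. Control 3 is also the library with the highest protein-coding share, 50.8%.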

How the results depend on the processing

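The scalings by TMM, by TMM from protein-coding genes and by quantiles, the edgeR test and the fit without short or repeated rows were chosen after seeing the data. The 150 called genes became 43 with the replicate number as a block (39 of them among the 150), 593 with DESeq2 (all 150 among them) and 57 against a fold of 1.5, and between 79 and 186 with 1 library left out. Scaling, filter, pseudocount and edgeR gave 121 to 184, the fit without chromosome X 138, and the fit without short or repeated rows 215. DESeq2's size factors were those of the authors, so that alternative moved nothing. The share of lower calls, 78.7%, was 67.4% with the block, 68.4% against a fold of 1.5, 67.5% without control 2 and 62.8% without control 3. The block effectively drops knockout 5, which has no partner (80 calls without that library and no block), and the cause of the remaining difference was not tested. The count of gene.human_ rows that fell, 17, was 7 with the block, 50 with DESeq2 and 10 to 28 with 1 library left out. Of 9 gene lists past the threshold, 0 passed with an estimated correlation, 2 with fry (HERVH-associated transcripts and mesendoderm markers, smallest adjusted p = 0.034), 16 without a filter and 9 to 17 with 1 library left out (17 without control 4, 15 without knockout 3). The proliferation list passed in both directions, lower without control 1 (adjusted p = 0.021) and higher without control 3 (0.016) and under quantile normalization (0.038), its adjusted p running from 0.016 to 0.83 with 1 library left out (adjusted p = 0.93 with an estimated correlation). Hypoxia and glycolysis turned to higher under quantile normalization (0.018, and adjusted p = 0.99 with an estimated correlation), and the cause of neither was tested. In the main fit the hypoxia and glycolysis median, -0.03, already lay above the central range of random lists matched on expression (-0.26 to -0.05). Endoderm passed as lower under quantile normalization (adjusted p = 0.029) and TMM from protein-coding genes (0.035), and WNT signalling under quantile normalization (0.045), with adjusted p = 0.32 and 0.53 with an estimated correlation. TMM from protein-coding genes moved the median of all tested rows from 0.01 to 0.11, and coding genes with a mean of at least 50 normalized counts from -0.10 to 0.00. The 9 lists that passed were lower under TMM, TMM from protein-coding genes and quantile normalization, and the lists were not run with upper quartile or log2(CPM + 1). Calls by chromosome passed in 0 to 2 tests with 1 library left out and in 0 otherwise. The 150 calls shared with the authors' table became 584 with DESeq2. Of 26 named genes called, 14 passed with the block (highest adjusted p = 0.20), 15 in all 9 fits with 1 library left out, and none changed direction in the settings tried. Those that missed the threshold numbered 10 without knockout 5, 9 each without control 1, control 2 and knockout 4, 8 without knockout 2, 6 each without control 3 and knockout 1, 5 without knockout 3, 3 without control 4, 3 with edgeR, 5 under quantile normalization and 1 under TMM from protein-coding genes. ESRG passed with DESeq2 (adjusted p = 0.040). Beyond the calls named beside their results, the block changed no other call among named genes and lists. At this depth and spread limma found 20 of 100 simulated 2-fold changes, which limits what can be said of genes that did not pass. Those simulated changes lay in genes with a mean of at least 50 normalized counts, without swings shared between genes.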

Other observations

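Several pairs of neighbouring genes changed together; these genes were picked after their values were seen. On chromosome 12, IRAK4, a kinase of Toll-like receptor signalling that lies beside PUS7L, rose from 2.50 ± 1.36 to 79.2 ± 10.99 normalized counts (log2 fold change 4.57, limma adjusted p = 0.00015). On chromosome X, TMEM230P1 (107939263 to 107939642) and NLRP3P1 (107974078 to 107985008) both fell. The log2 fold changes were -5.37 and -3.83 (limma adjusted p = 0.0094 and 0.0043). The zinc finger gene ZNF667 and its antisense partner ZNF667-AS1 fell by 1.76 and 1.78 on the log2 scale (limma adjusted p = 0.0028 and 0.0094). CRYAB, a small heat shock gene, fell by 2.14 on that scale (limma adjusted p = 0.019). It passed in 5 of 9 fits with 1 library left out and not with the block (adjusted p = 0.097). As exons of CRYAB overlap those of HSPB2, their reads may be shared and this pair may be 1 signal. Of 40 tested clustered protocadherin genes, cell surface adhesion genes on chromosome 5, PCDHA11 (-1.49), PCDHB15 (-2.05), PCDHGA11 (-1.82) and PCDHGB4 (-1.93) fell and 0 rose (6 lower when adjusted over the list alone, median -0.25, camera adjusted p = 8.9e-06, and adjusted p = 0.17 with an estimated correlation). With the block these 4 missed the threshold (limma adjusted p between 0.062 and 0.0997), and PCDHB15 (0.052) and PCDHGA11 (0.054) did so without control 2. The median of the protocadherins came to -0.40 without control 3. How reads are divided among the clustered protocadherin genes was not measured. Of 469 tested genes with ZNF symbols 1 rose and 7 fell, with a median of -0.05 (5 higher and 14 lower when adjusted over the list alone, camera adjusted p = 0.13), and the authors' deposited table calls 7 higher and 21 lower. That median came to -0.03 without control 1, 0.03 without control 3, -0.11 without control 4 and -0.01 without knockout 4.

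The lists marked by the authors were chosen on these samples and are not independent evidence of a direction. Of their EMT mark 11 rows were tested, 1 higher and 4 lower (median -1.14), of the defence mark 32, 1 higher and 9 lower (-0.85), of the differentiation mark 8, 1 higher and 1 lower (-1.63), and of the testis mark 3, 1 higher and 0 lower (3.15).

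All tests below except the splits of the libraries and the window test were chosen after the result was seen. Of 100 splits of the 9 libraries into 4 and 5, 1, the real one, gave 150 genes. The highest count of the other splits was 30. As the splits exchange passages of 1 clone per group, they speak only to the spread between passages. Among the 15 of these 100 splits that part all 4 pairs, too few for a share under 0.05, the highest other count was 9. With the pairing, chance is therefore not firmly excluded for the count. For the 9 gene lists 50 of 100 splits gave as many (highest other 19, from a split of control 1, control 2, control 3 and knockout 3 against the rest), so chance cannot be excluded for that count.

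The first pattern is the joint fall of the gene.human_ rows without the mark. Of 100 splits 1, the real one, gave 17 such rows (highest other 1) and 1 gave a median as far from 0 as 1.30 (highest other 1.21). A single library or the scaling cannot be the whole cause, since the median stayed at or below -1.07 in every scaling, tool and left-out library tried. Reads of the removed locus assigned to related rows stay open, because the unmarked rows lost 18.5 times as many normalized counts as the marked rows but how reads are divided among the rows was not measured. Whether the deletion or some other difference between the clones lowered them cannot be told apart with 1 clone per group, so an effect of the locus on related transcripts may be put forward only as an untested hypothesis.

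The second pattern is that called genes lie beside each other. Of 128 called genes with a position, 23 had a called gene of the same direction within 100 kb, against at most 12 in 1000 random sets matched on expression. Reads shared between overlapping genes are not the whole cause, because 11 had such a neighbour with a separate gene body (at most 8 in random sets). A gained or lost chromosome or large segment is argued against by the largest running median over 51 coding genes, 0.27 in size, where 1 extra copy would give 0.58. A window of 51 genes cannot show a gain or loss of only a few genes, which was not tested and stays open. An epigenetic difference between the clones in the regions of neighbouring calls may explain the pattern. With 1 clone per group such a difference cannot be told apart from the knockout.

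The third pattern is the lower pluripotency list, for which 4 of 100 splits gave a median as far from 0 as -0.58 (highest other 0.65) and 1 more came to 0.576, while the 15 splits that part all 4 pairs (highest other 0.45) are too few for a share under 0.05, so chance is not firmly excluded. A trend with expression in control 3 is not the whole cause, since without that library the median was -0.36, below the central 95% of matched lists (-0.08 to 0.11). More differentiated cells in the knockout cultures stay open, because the highest median of 4 lineage lists, -0.33 for ectoderm (-0.21 without control 2, -0.15 without control 3 and -0.54 without control 4), lay within the central 95% of matched lists (-0.38 to 0.22). Its member MAP2 was higher when adjusted over the list alone (log2 fold change 0.58, adjusted p = 0.037), while 4 of its 6 tested members had a negative log2 fold change. The other lineage medians lay below the central 95% of matched lists, whose lower ends were -0.45, -0.49 and -0.47. They were -0.80 for mesendoderm and mesoderm, -0.74 for endoderm (-0.30 without control 3) and -0.70 for trophectoderm and amnion. A swing that the pluripotency genes share between libraries may account for their lower median and stays open, because the adjusted p of that list was 0.32 with an estimated correlation. With 1 clone per group, an effect of the knockout was not separated from the clone.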
